A study of Arabidopsis thaliana with 8 samples.

How the data were processed

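Total RNA of pooled floral buds (stages 8 to 10) of Arabidopsis thaliana was treated with DNase and made into standard Illumina libraries, which were sequenced on an Illumina HiSeq instrument as 125 bp paired ends at a stated average depth of 30 M reads, per the labels' protocols. The genome build was TAIR10, per the submitters' processing notes. The aligner, the read counter, its strand setting, the annotation and the test behind the authors' comparison are not given in the sources used here. Samples were grouped by their titles and genotype labels into WT and amiRNACWIN24, with 4 biological replicates each. No batch or collection time is given in the labels.

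The authors deposited a table of RPKM values, which are reads normalised for transcript length and for mapped reads, with 1 column per library for 33977 genes, and a table of their own comparison with log2 fold changes, fold changes and p-values, per the file headers. The fold change the authors deposited is a signed score, which by its values is the negative reciprocal for a decrease. The comparison table has no value for 8097 genes and is quoted only as the authors' deposited table. Of the 33977 genes 32548 matched the TAIR10 annotation used here and 32532 had the same coordinates, and 7837 were at 0 in every library.

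The RPKM values moved in steps of 1 read. For each library the denominator that makes low values whole multiples of the value of 1 read was found, at 29.1, 27.6, 26.6 and 28.0 M in WT replicates 1 to 4 and 26.8, 25.6, 26.5 and 26.4 M in amiRNACWIN24 replicates 1 to 4. Low values, under 1000 reads in genes with matching coordinates and no overlap, came out whole within 0.05 reads for 99.6% to 99.7% per library. All 8 values came out whole for 32289 genes, with genes at 0 in every library included. For that count the tolerance widened with the number of reads, so it is no check of the highest values. A count of 0 allows up to 3 reads, a floor that covers counting error only. In CWINV2 1 read is worth 0.0161 RPKM in WT replicate 2, so differences of a few hundredths of an RPKM rest on single reads.

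Values were analysed as log2(RPKM + 0.5) for genes with a mean of at least 1 RPKM over the 8 libraries (19082 genes). The genotypes were compared with limma 3.58.1 in R 4.3.3 (moderated test with eBayes and a mean-variance trend, two-sided, genotype as the only term), with Benjamini-Hochberg adjustment over all genes tested, a threshold of 0.05 and no minimum fold. Cell wall invertases and STK were also compared by an exact two-sided permutation test over the 70 arrangements of the libraries. Gene lists with at least 3 tested members were tested with camera at a preset correlation of 0.01 and again with a correlation estimated per list, and with fry, which asks whether the genes of a list move one way on balance and does not compare them with other genes. Adjustment was over the 24 lists, and families were adjusted separately. Of the 24 lists 7 passed camera with the preset correlation. With the estimated correlation 0 passed and 1, the developmental receptor kinase list, had an unadjusted p under 0.05 (p = 0.046). The lowest adjusted p in fry was 0.00025, shared by the late pollen, developmental receptor kinase and clock lists. Families were taken from words in gene descriptions, and 27 of these words matched at least 10 tested genes; defensin, aquaporin and self-incompatibility matched fewer and were not tested. A family holds whatever its word matches: histone includes histone-modifying enzymes, disease resistance includes dirigent-like proteins, sugar transporter mostly nucleotide-sugar carriers, and thionin mostly enzymes named for methionine. Other values were computed with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots drawn with matplotlib 3.10.9.

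The lists, the tests, a first set of alternatives and the rule for the genes named were fixed before the data were examined. The rule takes CWINV2, CWINV4, STK and the other cell wall invertases, the 10 genes with the largest rise and the 10 with the largest fall among those that passed with no overlap between the groups, and up to 4 tested members with the smallest p from each list, 118 genes in all. Of these 115 were tested, 61 rose and 46 fell. This first set held pseudocounts of 0.1 and 1, no filter and a minimum of 5 RPKM, median-of-ratios scaling, quantile normalization, eBayes without a trend, array weights, the replicate number as a block, each library left out in turn, a minimum change of 1.5-fold and the estimated correlation. Chosen after seeing the data were removal of the exon length trend in each library (a natural spline with 4 degrees of freedom on log2 exon length), the same with GC content, leaving out genes that overlap another gene, voom on the recovered reads, and leaving out WT replicates 1 and 2.

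The procedure was tested on simulated data for this comparison, with 18998 genes, a dispersion of 0.02 and 200 changed genes. It recovered 46 of 78 genes changed 1.5-fold (59%), 54 of 56 changed 2-fold (96.4%) and all 66 changed 4-fold, and called 13 unchanged genes. Apart from the changed genes, all simulated libraries shared the same gene means, with no exon length trend and no library that stood apart. Its recovery and its false calls therefore do not cover those features of the data. Genes that overlap another gene on the other strand are marked as uncertain, because no strand setting is stated, as are near-identical copies.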

Results

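RNA was sequenced from pooled Arabidopsis thaliana floral buds of stages 8 to 10, taken from wild type (WT) and from transgenic line 4-3, which carries pSTK::amiRNACWIN24 and is called amiRNACWIN24 here. The construct places an artificial microRNA, named for the cell wall invertases CWINV2 and CWINV4, under the promoter of STK (SEEDSTICK), a MADS box gene of ovule identity. Cell wall invertases cleave sucrose outside the cell into glucose and fructose. The question was which transcripts differ when this activity is targeted where ovules begin to form. There were 4 biological replicates of each genotype, 8 libraries in all, and expression was deposited as RPKM for 33977 genes. The reads assigned to genes, recovered from the steps of the RPKM values, were 25.5, 26.7, 25.7 and 26.7 M in WT replicates 1 to 4 and 26.2, 22.5, 25.9 and 25.8 M in amiRNACWIN24 replicates 1 to 4. Fold changes are amiRNACWIN24 over WT on the log2(RPKM + 0.5) scale, which understates the change of low genes, and adjusted p-values are from limma.

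CWINV4 (AT2G36190; chromosome 2, 15174624 to 15178086 in TAIR10) was lower in every amiRNACWIN24 library than in any WT library. Its level was 26.9 ± 2.61 RPKM in WT and 13.8 ± 1.76 RPKM in amiRNACWIN24 (SD, n = 4 each), a log2 fold change of -0.95 (limma adjusted p = 0.00015; exact two-sided permutation p = 0.029, the smallest that 70 arrangements allow). CWINV2 (AT3G52600; chromosome 3, 19506891 to 19509412) was near the detection limit in 7 of the 8 libraries. WT replicate 1 held 2.75 RPKM, from 180 reads, while the other WT replicates held 0.0161, 0.0167 and 0.0317 RPKM, from 1, 1 and 2 reads, and amiRNACWIN24 held 0.0166, 0.105, 0.0504 and 0.0674 RPKM, from 1, 6, 3 and 4 reads. A difference in CWINV2 was not detectable at this depth (difference of log2 means -0.56, exact permutation p = 0.94), and without WT replicate 1 its sign turned to 0.10 (exact permutation p = 0.14). CWINV2 also overlaps the ubiquitin extension gene UBQ1 (561 ± 54.6 RPKM in WT) on the other strand, so its few reads are uncertain in origin. UBQ1 itself was at 496 RPKM in WT replicate 1, against 602, 611 and 536 RPKM in WT replicates 2 to 4. A higher UBQ1 level therefore does not go with the 180 reads of CWINV2 there. In that library 143 genes, pollen genes among them, also stood over 4-fold above every other library.

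STK itself (AT4G09960; chromosome 4, 6236375 to 6241281), whose promoter drives the construct, fell from 9.82 ± 1.44 RPKM in WT to 0.599 ± 0.156 RPKM in amiRNACWIN24 (SD, n = 4 each). The log2 fold change was -3.23 (limma adjusted p = 1.6e-06; exact permutation p = 0.029), and the authors' deposited table gives -4.37. STK shares 186 bp with AT4G09950 on the other strand, a gene that rose from 3.40 ± 0.456 to 4.44 ± 0.490 RPKM (log2 0.34, limma adjusted p = 0.035). Among the other genes named as cell wall invertases, CWINV3 rose from 10.8 ± 0.529 to 16.0 ± 1.31 RPKM (log2 0.54, limma adjusted p = 5e-04). It still passed, at 0.27, with the trend in fold change over exon length removed. CWINV1 stood at 4.91 ± 2.15 RPKM in WT and 4.50 ± 2.03 RPKM in amiRNACWIN24 and did not pass the test (limma adjusted p = 0.79). CWINV5 held 0.0542 ± 0.0411 and 0.0634 ± 0.0385 RPKM, and CWINV6 held 0.0427 ± 0.0261 and 0.0125 ± 0.0158 RPKM, in WT and amiRNACWIN24, both too low to be tested. CWINV5 overlaps a gene on the other strand and is uncertain. By annotation CWINV6 is a fructan exohydrolase, so the list follows gene names and not measured activity. Of the 3 genes of this list that were tested, 1 rose, 1 fell and 1 did not pass, with the same counts adjusted over the list alone. For the cell wall invertase list, camera gave an adjusted p = 0.74 (adjusted p = 0.93 with an estimated correlation).

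**Figure D1:**
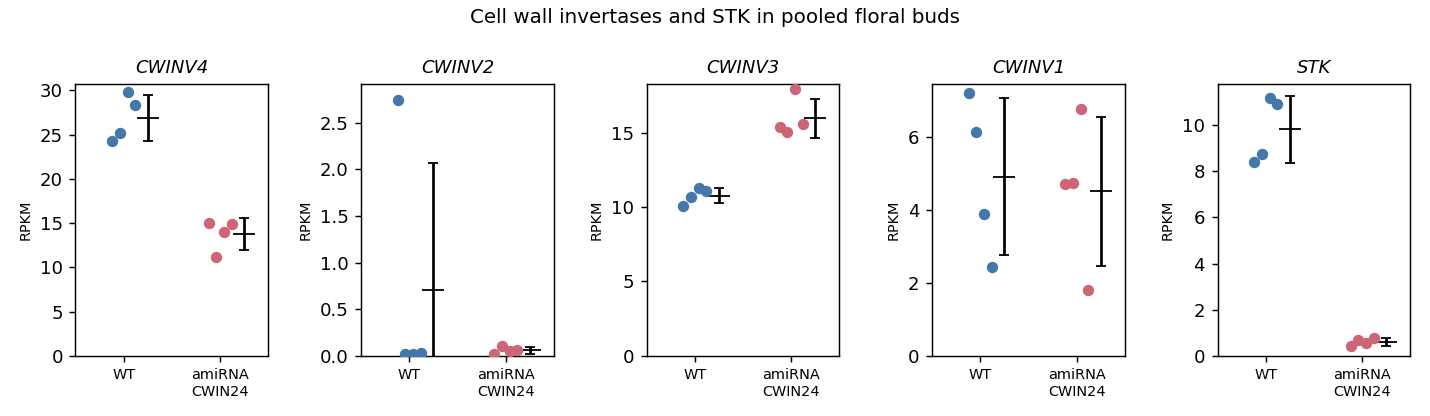
RPKM (linear axis from 0) of CWINV4, CWINV2, CWINV3, CWINV1 and STK in each WT (blue) and amiRNACWIN24 (red) library, 4 per genotype, with the mean and SD beside the points. CWINV4 and STK are lower in all 4 amiRNACWIN24 libraries, CWINV2 reads above 1 RPKM in WT replicate 1 alone (2.75), and the SD bar of CWINV2 in WT runs past the axis at 0.

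Across the transcriptome, RALFL8 and AGP6, an arabinogalactan protein gene of pollen, were among those that fell most, and IGMT5, CYP79B2 and the clock-regulated FKF1 were among those that rose most. Of 19082 genes with a mean of at least 1 RPKM, 9609 differed at a limma adjusted p under 0.05, of which 5611 rose and 3998 fell in amiRNACWIN24. The groups did not overlap for 8281 of the 9609, and for 45.9% of all tested genes against the 2.86% that chance gives. The change was at least 1.5-fold for 3785 genes, 2121 up and 1664 down. The first principal component held 67.4% of the variance and separated the genotypes, and pairwise correlations across genes were 0.969 to 0.991 within WT, 0.982 to 0.992 within amiRNACWIN24 and 0.905 to 0.953 between them.

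Fold changes ran with transcript length. The decile of genes with the shortest exon length (median 755 nt) had a median log2 fold change of -0.49, with 64.4% of its genes down and 2.3% up, and the decile with the longest (median 3859 nt) had a median of 0.61, with 87.9% up and 2.1% down. The slope of log2 RPKM, taken against the gene means, per doubling of exon length was -0.16, -0.37, -0.24 and -0.13 in the WT libraries and 0.19, 0.22, 0.24 and 0.25 in the amiRNACWIN24 libraries (difference 0.449, exact two-sided permutation p = 0.029). When the length trend was removed, within each library, an alternative chosen after seeing the data, 5573 genes differed, 2877 up and 2696 down, and 3811 of the original calls were kept with the same sign. For many of the gene groups described next the counts after this removal are given beside the counts from the values as deposited.

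**Figure D2:**
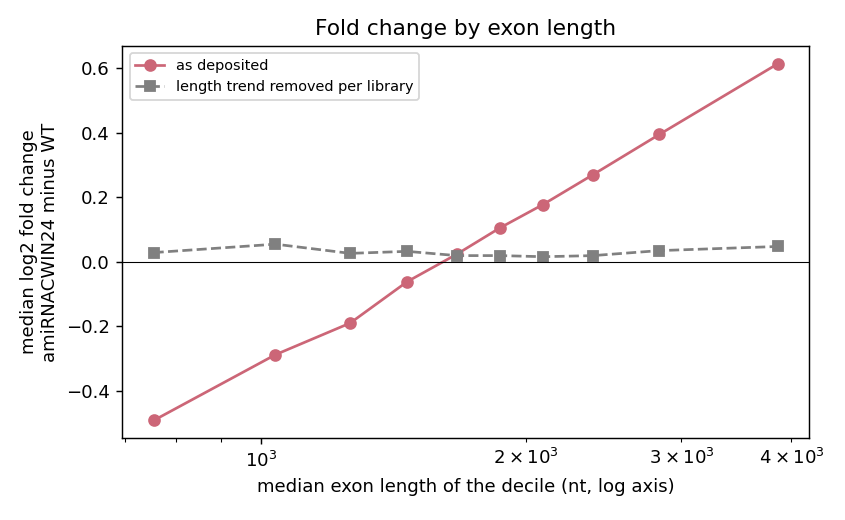
Median log2 fold change (amiRNACWIN24 minus WT) of the tested genes in 10 bins of exon length, against the median exon length of each bin (nt, log axis). The values as deposited (red circles) run from -0.49 in the shortest bin to 0.61 in the longest, and after removal of the length trend in each library (grey squares) they lie between 0.02 and 0.06.

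Among the genes with the largest fall, RALFL8, a RALF-like peptide gene, fell from 172 ± 86.3 to 9.53 ± 2.65 RPKM (log2 -3.99), AGP6, an arabinogalactan protein of pollen, from 53.5 ± 32.2 to 2.54 ± 0.850 RPKM (log2 -3.97), and LCR17, a small cysteine-rich protein gene, from 30.0 ± 24.1 to 0.825 ± 0.516 RPKM (log2 -4.14; SD, n = 4 in each group). In limma the adjusted p was 2.9e-05 to 0.00042. AT4G13230, of the late embryogenesis abundant family, fell by 4.19 on the log2 scale, AT3G28840 by 4.08 and AT5G39493, of the self-incompatibility S1 family, by 4.00. WT replicates 1 and 2 stood above replicates 3 and 4 in these genes, with 49.5 and 52.1 against 6.87 and 11.6 RPKM for LCR17 and 69.5 and 90.6 against 21.3 and 32.6 RPKM for AGP6. Without both, left out after seeing the data, RALFL8, AGP6, LCR17, AT4G13230, AT3G28840 and AT5G39493 still passed, at log2 -3.32, -3.19, -2.92, -3.29, -2.83 and -3.06. AT1G38065 was listed at 0 in all amiRNACWIN24 libraries and held 4.07, 10.96, 9.70 and 9.66 RPKM in WT. AT3G14340 was likewise listed at 0 in amiRNACWIN24, with 9.74, 18.4, 16.6 and 5.71 RPKM in WT. DIR1 held 231, 198, 111 and 106 RPKM in WT, and was listed at 0 in amiRNACWIN24 except for 14.4 RPKM in replicate 3. AT5G08820 held 7.17, 14.1, 14.5 and 9.52 RPKM in WT and was listed at 0 except for 0.239 RPKM in amiRNACWIN24 replicate 3. RALFL8, AT3G14340, DIR1 and AT5G08820 overlap a gene on the other strand and are uncertain. The gene that RALFL8 overlaps was listed at 0 in every library. In the authors' deposited table DIR1 has a log2 fold change of -1.27 and AT5G08820 has 1.36. That table gives -4.26 for RALFL8, and -2.37 with an FDR of 0.59 for AT3G14340.

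Among the genes that rose most, IGMT5, an indole glucosinolate methyltransferase, went from 2.49 ± 1.04 to 21.7 ± 2.66 RPKM (log2 2.95), and CYP79B2, which converts tryptophan to indole-3-acetaldoxime, from 8.19 ± 1.83 to 36.3 ± 5.99 RPKM (log2 2.09). FKF1, a blue light receptor of the photoperiod pathway, rose from 2.05 ± 0.354 to 11.2 ± 2.57 RPKM (log2 2.19; SD, n = 4 in each group). Adjusted p from limma ran from 1.3e-05 to 1.5e-05 for these genes. AT5G28400 rose by 1.99 on the log2 scale, AT5G23240, a DnaJ domain gene, by 1.99, AT1G05087 by 1.95 and AT1G55980 by 1.93. AT1G55673 was listed at 0 in all WT libraries and held 138, 84.7, 58.8 and 129 RPKM in amiRNACWIN24; it overlaps PSAG, a photosystem I gene at 1189 ± 175 RPKM in WT, on the other strand. AT4G02720 (log2 3.22) and AT3G22121 (log2 2.36) also overlap genes on the other strand, as do IGMT5, FKF1 and AT5G23240, and are uncertain. The authors' deposited table gives log2 fold changes of 0.61, 0.07 and 0.78 for AT1G55673, AT4G02720 and AT3G22121. For IGMT5, FKF1 and AT5G23240 it gives 3.07, 2.36 and 2.31, close to the values here.

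Late pollen and pollen coat genes fell together. Of 11 tested, 9 fell, 0 rose and 2 did not pass, with the same counts adjusted over the list alone. VGD1, a pectin methylesterase of pollen tubes, fell from 138 ± 38.2 to 19.3 ± 5.06 RPKM (log2 -2.80), the oleosin-like coat protein genes GRP14 and GRP16 fell by 1.79 and 1.94 on the log2 scale, and AGL104, a MADS box gene of pollen, fell from 6.95 ± 0.747 to 1.65 ± 0.158 RPKM (log2 -1.79; SD, n = 4 in each group). Their limma adjusted p was 8.1e-06 to 6.2e-05 for the 4 genes. GRP16 overlaps a gene on the other strand. The list passed camera (adjusted p = 1.8e-06; adjusted p = 0.55 with an estimated correlation), and 9 of the 11 also fell with the length trend removed. WT replicate 1 stood apart here: 143 genes, the pollen genes VGDH1 (18.4 RPKM) and BCP1 (11.7 RPKM) among them, exceeded their level in every other library over 4-fold, against at most 3 genes in any other library. VGD1 stood at 162 and 176 RPKM in WT replicates 1 and 2 and at 93.2 and 120 RPKM in replicates 3 and 4. Without WT replicates 1 and 2, left out after seeing the data, the median of the list was -1.54 against -1.51 with all libraries.

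Genes of the tapetum and pollen wall, which act earlier in anther development, went both ways. Of 15 tested, 7 rose, 3 fell and 5 did not pass, and 10 rose and 3 fell adjusted over the list alone. For the tapetum list, camera gave an adjusted p = 0.28 (adjusted p = 0.93 with an estimated correlation). The count of rises was 3 without WT replicate 1 or 2, 2 without amiRNACWIN24 replicate 1 or 4, 11 without WT replicate 3 and 10 without amiRNACWIN24 replicate 3, and the falls numbered 1 to 3 across these. With no filter 4 rose and 2 fell, under quantile normalization 9 rose and 1 fell, without amiRNACWIN24 replicate 2, 6 rose and 1 fell, and without both WT replicates 1 and 2, 1 rose and 3 fell. ACOS5, a sporopollenin enzyme, rose from 29.7 ± 20.5 to 90.8 ± 37.2 RPKM (log2 1.75), the fatty acyl reductase MS2 rose by 1.38 and the regulator MS1 by 1.204 on the log2 scale, while QRT3, a polygalacturonase that frees pollen from the tetrad, fell by 0.64 (n = 4 in each group). The limma adjusted p ranged from 0.0068 to 0.019. When the length trend was removed, 2 rose and 2 fell, while the list median was 1.204 before and 1.21 after. The calls of MS2 and MS1 ended with folds and errors close to those before: MS2 went from 1.38 (SE 0.409) to 1.21 (SE 0.423) and MS1 from 1.204 (SE 0.366) to 1.01 (SE 0.387), and with fewer genes passing overall the adjustment is stricter. The call of MS1 also ended without amiRNACWIN24 replicate 1 (log2 1.05, adjusted p = 0.055) or replicate 4 (log2 1.05, adjusted p = 0.052), and without WT replicates 1 and 2 together (log2 0.76), as did that of MS2 (log2 0.72), while ACOS5 still passed (log2 1.14). In the meiosis list 0 of 9 rose, 2 fell and 7 did not pass, and 1 fell adjusted over the list alone (camera adjusted p = 0.74; adjusted p = 0.94 with an estimated correlation); its median was 0.087 while its mean was -0.042 and camera ranked it down. SYN1, a meiotic cohesin gene that overlaps a gene on the other strand, fell from 2.58 ± 0.505 to 0.947 ± 0.154 RPKM (log2 -1.08), and OSD1 fell by 0.39, a call lost with the length trend removed (log2 -0.26), with no filter (log2 -0.39) and without WT replicate 2, 3 or 4 or amiRNACWIN24 replicate 2 or 3 (log2 from -0.39 to -0.31). Of the meiosis genes 3 rose and 2 fell in eBayes without a trend, 2 rose and 2 fell under quantile normalization, 1 rose and 2 fell with array weights or voom, and 1 rose and 1 fell with no filter or without WT replicate 4. With 0 rises, 1 fell without WT replicate 2 or 3 or amiRNACWIN24 replicate 2 or 3, without overlapping genes and with the length trend removed. ZYP1B held 0.958 ± 0.279 RPKM in WT and 1.39 ± 0.181 in amiRNACWIN24, and MSH5 held 0.925 ± 0.185 and 1.304 ± 0.229, and neither passed.

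Sugar transporters also went both ways, with the steepest falls in hexose carriers. Of 28 tested, 5 rose, 9 fell and 14 did not pass, as they did adjusted over the list alone. For the sugar transporter list, camera gave an adjusted p = 0.14 (adjusted p = 0.83 with an estimated correlation). STP9, a glucose carrier of pollen, fell from 68.4 ± 25.6 to 7.04 ± 2.79 RPKM (log2 -3.20), STP6 from 17.5 ± 6.89 to 1.79 ± 0.699 RPKM (log2 -2.96), STP2 from 76.3 ± 12.1 to 33.4 ± 5.33 RPKM (log2 -1.18) and SWEET7 from 26.0 ± 4.97 to 10.7 ± 1.27 RPKM (log2 -1.23; SD, n = 4 in each group). In limma the adjusted p was 5.2e-05 to 0.00018. STP9 overlaps a gene on the other strand. The counts were the same, 5 up and 9 down, with the length trend removed. Without amiRNACWIN24 replicate 3, 3 rose and 9 fell, and under median-of-ratios scaling 3 rose and 10 fell.

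Of the other genes of sucrose cleavage, 7 of 16 rose, 0 fell and 9 did not pass, also when adjusted over the list alone. This list also holds C/VIF1 and C/VIF2, which are genes of invertase inhibitors. For the sucrose cleavage list, camera gave an adjusted p = 0.14 (adjusted p = 0.66 with an estimated correlation). It passed with array weights (adjusted p = 0.046; adjusted p = 0.62 with an estimated correlation) and without WT replicates 1 and 2 (adjusted p = 0.028; adjusted p = 0.93 with an estimated correlation), over alternatives from 0.028 to 0.66, with 9 rises and 0 falls in each. The sucrose synthase SUS6 rose from 2.65 ± 0.153 to 4.04 ± 0.271 RPKM (log2 0.53), and the neutral invertases CINV2, INV-E and A/N-InvA rose by 0.47, 0.35 and 0.30 on the log2 scale (n = 4 in each group). Adjusted p from limma ran from 0.0016 to 0.012. With the length trend removed 2 rose and 3 fell, and the calls of SUS6, INV-E and A/N-InvA ended at log2 0.040, 0.016 and 0.018. The 2 rises were CINV2 (log2 0.25) and the inhibitor gene C/VIF2 (log2 0.57). The 3 falls were the invertase genes CINV1, A/N-InvB and A/N-InvH (log2 -0.30, -0.40 and -0.63). The call of A/N-InvA also ended without WT replicates 1 and 2 together (log2 0.28). In the starch and sugar storage list, which holds genes of starch synthesis and of starch breakdown, 6 of 9 rose. None fell (0) and 3 did not pass, also adjusted over the list alone. The beta-amylases BAM3 and BAM5 rose from 65.1 ± 3.39 to 164 ± 24.2 RPKM (log2 1.31) and from 58.8 ± 16.5 to 156 ± 31.1 RPKM (log2 1.41), GPT2, a glucose 6-phosphate carrier of plastids, from 1.54 ± 0.936 to 5.53 ± 1.56 RPKM (log2 1.65), and PGM1 by 0.44 on the log2 scale (SD, n = 4 in each group). Their limma adjusted p was 2.5e-05 to 0.0022. The list passed camera (adjusted p = 0.023; adjusted p = 0.55 with an estimated correlation), and its call ended with the length trend removed (adjusted p = 0.071; 3 rose, 1 fell, and PGM1 at log2 0.16 did not pass), with a minimum of 5 RPKM (0.059) and without overlapping genes (0.095), over alternatives that ranged from 0.0074 to 0.55. With the length trend removed GBSS1, APL1, APL3 and APS1 stood at log2 0.048, 0.097, 0.13 and 0.16 and did not pass. A/N-InvA and BAM3 overlap genes on the other strand.

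In sugar sensing and signalling 7 of 11 rose, 2 fell and 2 did not pass, also adjusted over the list alone. For the sugar sensing list, camera gave an adjusted p = 0.28 (adjusted p = 0.83 with an estimated correlation). TOR, the kinase of the nutrient pathway, rose from 8.03 ± 2.77 to 17 ± 1.01 RPKM (log2 1.09), TPS1, which makes trehalose 6-phosphate, rose by 0.50 and the G protein subunit GPA1 by 0.43, while HKL3, a hexokinase-like gene, fell from 4.68 ± 0.331 to 1.12 ± 0.283 RPKM (log2 -1.69; SD, n = 4 in each group). The limma adjusted p ranged from 2.6e-05 to 0.0023. With the length trend removed 1 rose and 2 fell, TOR stood at 0.067 and TPS1, which overlaps genes on the other strand, at -0.25, and neither these nor GPA1 (0.18) passed. Among 16 genes of the sugar starvation response 3 rose, 3 fell and 10 did not pass, also adjusted over the list alone. For the starvation list, camera gave an adjusted p = 0.86 (adjusted p = 0.94 with an estimated correlation). Without WT replicate 1, 5 rose and 2 fell, as without WT replicates 1 and 2 together, and with array weights 7 rose and 2 fell. DIN10 rose by 0.94 and TPS10 by 0.54 on the log2 scale, whereas bZIP1 fell by 0.87 and AKINBETA1, a SnRK1 subunit, fell by 0.53 (n = 4 in each group). In limma the adjusted p was 0.001 to 0.0043. With the length trend removed 1 rose and 2 fell, and the calls of DIN10 (log2 0.52), which overlaps a gene on the other strand, and TPS10 (log2 -0.086) ended, with bZIP1 at -0.45.

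STK was the largest change among the floral organ and ovule identity MADS genes. Of 16 tested, 1 rose, 3 fell and 12 did not pass, also adjusted over the list alone. For the identity MADS list, camera gave an adjusted p = 0.28 (adjusted p = 0.83 with an estimated correlation). SHP2, a close relative of STK, fell from 15.5 ± 0.730 to 12.1 ± 1.36 RPKM (log2 -0.35), PI, a petal and stamen gene, from 258 ± 24.2 to 206 ± 9.84 RPKM (log2 -0.32), and CAL rose by 0.38 on the log2 scale (SD, n = 4 in each group). Adjusted p from limma ran from 0.0046 to 0.013. Under median-of-ratios scaling 5 fell and 1 rose, and under quantile normalization 2 fell and 3 rose. After removal of the length trend 1 rose and 2 fell, with CAL at 0.60. The 2 falls were STK (log2 -3.48) and AG (log2 -0.28), which had not passed before. The calls of SHP2, which overlaps a gene on the other strand, and PI ended with the length trend removed (log2 -0.15 and -0.13), and that of PI also under quantile normalization (log2 -0.0063).

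Among genes of ovule initiation and development 12 of 24 rose, 4 fell and 8 did not pass, also adjusted over the list alone. For the ovule list, camera gave an adjusted p = 0.14 (adjusted p = 0.83 with an estimated correlation). The corepressor genes SEU and LUG rose from 10.1 ± 2.87 to 24.3 ± 1.77 RPKM (log2 1.26) and from 23.4 ± 2.40 to 39.9 ± 2.62 RPKM (log2 0.76), and the class III HD-ZIP genes REV and PHV rose by 0.65 and 0.50 on the log2 scale (SD, n = 4 in each group). Their limma adjusted p was 0.00018 to 0.001. Once corrected for length, 5 rose and 3 fell, SEU stood at 0.72 and LUG at 0.25, and the calls of REV (0.16) and PHV (0.091) ended; SEU and REV overlap a gene on the other strand. The 4 that fell, named here after their values were seen, were INO, a gene of the outer integument (log2 -1.22), WUS, which acts in the nucellus (log2 -0.82), ATS (log2 -0.53) and SPL/NZZ, needed for sporocytes (log2 -0.35; limma adjusted p from 0.0039 to 0.031). The calls of INO (log2 -0.98, adjusted p = 0.087) and SPL/NZZ (log2 -0.17, adjusted p = 0.13) ended with the length trend removed. The falls numbered 2 without WT replicate 2 or 3 or amiRNACWIN24 replicate 3, and 1 without amiRNACWIN24 replicate 2. In the carpel and carpel margin list 6 of 25 rose, 0 fell and 19 did not pass, and 3 rose adjusted over the list alone. For the carpel list, camera gave an adjusted p = 0.29 (adjusted p = 0.93 with an estimated correlation). STY2 rose from 2.59 ± 0.179 to 4.18 ± 0.107 RPKM (log2 0.60), NGA3 rose by 0.69, SPT by 0.47 and NGA1 by 0.33 on the log2 scale (n = 4 in each group). The limma adjusted p ranged from 0.0007 to 0.026, and the call of NGA1 ended without amiRNACWIN24 replicate 1 (log2 0.32), 3 (0.30) or 4 (0.31), and without both WT replicates 1 and 2 (0.23). The rises numbered 4, with 1 fall, without WT replicate 1, and 3 without amiRNACWIN24 replicate 1 or 4. With array weights 5 rose and 2 fell, and without WT replicates 1 and 2 together 3 rose and 1 fell. Once corrected for length, 9 rose, 1 fell and the list passed camera (adjusted p = 0.011, over alternatives from 0.0097 to 0.93; adjusted p = 0.81 with an estimated correlation).

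Cytokinin genes went both ways. Of 22 tested, 7 rose, 9 fell and 6 did not pass, also adjusted over the list alone. For the cytokinin list, camera gave an adjusted p = 0.28 (adjusted p = 0.83 with an estimated correlation). The type-A response regulators ARR16, ARR6 and ARR9, which are induced by cytokinin and damp its signal, fell from 25.1 ± 1.85 to 11.2 ± 1.68, from 16.8 ± 0.857 to 8.85 ± 0.237 and from 14.9 ± 1.18 to 8.04 ± 0.632 RPKM (log2 -1.13, -0.89 and -0.85), and the receptor gene AHK2 rose from 7.21 ± 1.09 to 14.7 ± 2.22 RPKM (log2 0.98; SD, n = 4 in each group). In limma the adjusted p was 2.5e-05 to 0.0003. Once corrected for length, 3 rose, 9 fell, AHK2 stood at 0.34 and the list passed camera in the downward direction (adjusted p = 0.028, over alternatives from 0.028 to 0.91; adjusted p = 0.29 with an estimated correlation). ARR6 and ARR9 overlap a gene on the other strand.

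In auxin response 16 of 41 genes rose, 8 fell and 17 did not pass, also adjusted over the list alone. For the auxin response list, camera gave an adjusted p = 0.65 (adjusted p = 0.94 with an estimated correlation). The auxin response factors ARF6, ARF2 and ARF4 rose from 46.3 ± 6.72 to 88.7 ± 4.54, from 67.5 ± 7.91 to 117 ± 5.61 and from 11.9 ± 0.851 to 20.2 ± 0.950 RPKM (log2 0.94, 0.80 and 0.74), and IAA5, an auxin-induced repressor gene that overlaps a gene on the other strand, fell from 4.86 ± 0.965 to 1.24 ± 0.0549 RPKM (log2 -1.60; SD, n = 4 in each group). Adjusted p from limma ran from 3.6e-05 to 0.00019. Once corrected for length, 8 rose and 10 fell, and ARF6, ARF2, ARF4 and IAA5 stood at 0.36, 0.25, 0.30 and -1.10. In auxin synthesis and transport 9 of 18 rose, 3 fell and 6 did not pass, also adjusted over the list alone. For the auxin transport list, camera gave an adjusted p = 0.28 (adjusted p = 0.83 with an estimated correlation). The transporter genes ABCB19, ABCB1 and LAX1 rose by 0.72, 0.52 and 0.49 on the log2 scale and the kinase gene PID by 0.65 (n = 4 in each group). Their limma adjusted p was 0.0002 to 0.0029. Once corrected for length, 3 rose and 4 fell, the call of ABCB19 ended (0.097) and ABCB1 stood at -0.16 without passing, with LAX1 at 0.22.

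All 26 developmental receptor kinases tested rose, also adjusted over the list alone. THE1, which senses the state of the cell wall, rose from 11.2 ± 0.941 to 23.9 ± 2.31 RPKM (log2 1.06), the brassinosteroid receptor BRI1 from 19.2 ± 1.84 to 38.4 ± 3.40 RPKM (log2 0.98), HERK1 from 8.64 ± 0.592 to 15.3 ± 0.653 RPKM (log2 0.79) and the meristem receptor CLV1 from 9.03 ± 0.552 to 15.6 ± 0.600 RPKM (log2 0.76; SD, n = 4 in each group). The limma adjusted p ranged from 3.8e-05 to 7.6e-05. The list passed camera (adjusted p = 9.8e-09; adjusted p = 0.55 with an estimated correlation). These are long transcripts (median exon length 3466 nt), and with the length trend removed 9 of 26 rose and 0 fell, with THE1, BRI1, HERK1 and CLV1 at 0.61, 0.35, 0.35 and 0.26. HERK1 overlaps genes on the other strand.

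Photosynthesis genes of green tissue fell: 10 of 11 fell, 0 rose and 1 did not pass, also adjusted over the list alone. LHCB1.1 and LHCB1.2, light-harvesting proteins of photosystem II, fell from 1881 ± 32.4 to 1032 ± 140 RPKM (log2 -0.88) and by 0.74 on the log2 scale, and LHCB2.1 and LHCB2.2 fell by 0.75 and 0.61 (SD, n = 4 in each group). In limma the adjusted p was 0.00025 to 0.00073. Both pairs are near-identical copies whose shares of the reads are uncertain. The list passed camera (adjusted p = 3.9e-05; adjusted p = 0.66 with an estimated correlation), its call ended under quantile normalization (adjusted p = 0.13, over alternatives from 4.7e-06 to 0.66), where 5 genes fell and LHCB1.1, LHCB1.2, LHCB2.1 and LHCB2.2 stood at -0.43, -0.34, -0.40 and -0.25, and 7 fell with the length trend removed, with LHCB2.2 at -0.33. Transcripts encoded in the organelles fell as well, from low levels: 17 of 55 chloroplast-encoded genes fell, 0 rose and 38 did not pass, with 14 down adjusted over the list alone. For the chloroplast list, camera gave an adjusted p = 1.6e-06 (adjusted p = 0.83 with an estimated correlation). ATPE fell from 11.4 ± 1.19 to 3.94 ± 2.03 RPKM (log2 -1.53), RPL32 and RPL22 fell by 1.40 and 1.23 on the log2 scale, and PSAJ held 4.33, 4.03, 5.58 and 6.34 RPKM in WT and was listed at 0 in amiRNACWIN24 except for 0.290 RPKM in replicate 2 (limma adjusted p from 8.1e-06 to 0.00093). Of 33 mitochondria-encoded genes 12 fell, 0 rose and 21 did not pass, with 11 down adjusted over the list alone (camera adjusted p = 2.5e-05; adjusted p = 0.83 with an estimated correlation), and the call ended with a minimum of 5 RPKM (adjusted p = 0.06, over alternatives from 5.7e-12 to 0.83). RPSL2, ORF111D, ORF149 and ORF262 fell by 1.56, 1.28, 0.96 and 0.87 on the log2 scale (n = 4 in each group). Adjusted p from limma ran from 0.00015 to 0.0036. Chloroplast-encoded genes took 0.121%, 0.031%, 0.034% and 0.068% of the RPKM sum in the WT libraries and 0.011%, 0.127%, 0.013% and 0.013% in the amiRNACWIN24 libraries, so amiRNACWIN24 replicate 2 was the highest of the 8 libraries. Without it 47 of 55 chloroplast-encoded and 29 of 33 mitochondria-encoded genes fell, and with array weights 41 and 24 fell.

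Defence and jasmonate genes rose: 8 of 12 rose, 0 fell and 4 did not pass, and 9 rose adjusted over the list alone. LOX2, a lipoxygenase of jasmonate synthesis, rose from 279 ± 18.18 to 605 ± 39.1 RPKM (log2 1.11), the jasmonate-induced VSP1 from 1695 ± 351 to 3071 ± 74.1 RPKM (log2 0.88), JAZ10 by 0.85 and EDS1, a regulator of immunity, by 0.73 on the log2 scale (SD, n = 4 in each group). Their limma adjusted p was 2.5e-05 to 0.0014. VSP1 is close in sequence to VSP2, and JAZ10 overlaps a gene on the other strand. The list passed camera (adjusted p = 0.0071; adjusted p = 0.66 with an estimated correlation), and 6 rose with the length trend removed, when LOX2 stood at 0.67 and EDS1 at 0.44.

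All 12 circadian clock genes tested changed, 7 up and 5 down, also adjusted over the list alone. For the clock list, camera gave an adjusted p = 0.28 (adjusted p = 0.83 with an estimated correlation). PRR5, TOC1, GI and ELF3, which peak from afternoon to evening, rose from 8.56 ± 1.11 to 29.2 ± 3.55, from 12.5 ± 0.730 to 30.8 ± 3.41, from 11.7 ± 0.802 to 26.7 ± 1.499 and from 12.9 ± 1.16 to 25.02 ± 1.47 RPKM (log2 1.71, 1.26, 1.16 and 0.93; SD, n = 4 in each group). The limma adjusted p ranged from 9.5e-06 to 4.9e-05. The 5 that fell, named here after their values were seen, were CCA1, LHY, PRR9, RVE8 and BOA, with log2 fold changes of -0.55, -0.82, -0.37, -0.49 and -0.79. Once corrected for length, 5 rose and 5 fell, GI and ELF3 stood at 0.54 and 0.59, and CCA1, LHY and BOA at -0.88, -1.30 and -1.30. ELF3 overlaps genes on the other strand. In the heat and abiotic stress list 2 of 7 rose, 1 fell and 4 did not pass, also adjusted over the list alone. For the heat and stress list, camera gave an adjusted p = 0.89 (adjusted p = 0.94 with an estimated correlation). KIN1, a cold-induced gene, fell from 570 ± 78.0 to 164 ± 32.7 RPKM (log2 -1.80), RD29A rose from 17.8 ± 4.61 to 37.1 ± 3.70 RPKM (log2 1.07) and ADH1 rose by 0.61 on the log2 scale (SD, n = 4 in each group). In limma the adjusted p was 2.5e-05 to 0.014. HSP101 held 3.65 ± 0.421 RPKM in WT and 4.33 ± 0.388 in amiRNACWIN24 and did not pass; ADH1 and HSP101 overlap a gene on the other strand.

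Cell cycle genes went both ways, with counts that moved with single libraries. Of 22 cell cycle genes 3 rose, 3 fell and 16 did not pass, and 2 rose and 0 fell adjusted over the list alone. For the cell cycle list, camera gave an adjusted p = 0.74 (adjusted p = 0.94 with an estimated correlation). The falls numbered 7 under median-of-ratios scaling, under quantile normalization and without WT replicate 1, and 0 without any of WT replicates 2 to 4 or amiRNACWIN24 replicates 1 to 3, where limma still called 2 to 4 rises. With array weights 6 fell and 4 rose, without WT replicates 1 and 2 together 7 fell and 1 rose, and eBayes without a trend gave 1 fall and 3 rises. After removal of the length trend 1 gene rose and 1 fell. The replication licensing genes MCM2, MCM6 and MCM3 rose by 0.62, 0.54 and 0.46 on the log2 scale and CDKB2;1, which overlaps a gene on the other strand, fell by 0.39 (n = 4 in each group). Adjusted p from limma ran from 0.004 to 0.033, and with the length trend removed the calls of all 4 ended (log2 0.19, 0.17, 0.062 and -0.24). The call of MCM3 also ended without WT replicate 1 or 2 or amiRNACWIN24 replicate 1 or 4 (log2 from 0.36 to 0.45) and without both WT replicates 1 and 2 (log2 0.25), as did that of MCM6 (log2 0.34). That of CDKB2;1 ended without WT replicate 2, 3 or 4 or amiRNACWIN24 replicate 1, 2 or 3 (log2 from -0.40 to -0.33). None of the 5 flavonoid genes tested passed in limma, over all genes or adjusted over the list alone, and none had an unadjusted p under 0.05; limma with voom weights on recovered reads passed 0 as well. Exceptions included quantile normalization, under which 2 rose, and leaving out WT replicate 1, without which 1 gene fell. For the flavonoid list, camera gave an adjusted p = 0.74 (adjusted p = 0.94 with an estimated correlation). CHS held 263 ± 59.5 RPKM in WT and 302 ± 45.6 in amiRNACWIN24, F3H held 66.9 ± 12.9 and 77.3 ± 14.9, FLS1 held 112 ± 24.3 and 139 ± 29.8, and TT7 held 17.1 ± 3.93 and 22.0 ± 4.62 RPKM (SD, n = 4 in each group); CHS and F3H overlap a gene on the other strand.

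**Figure D3:**
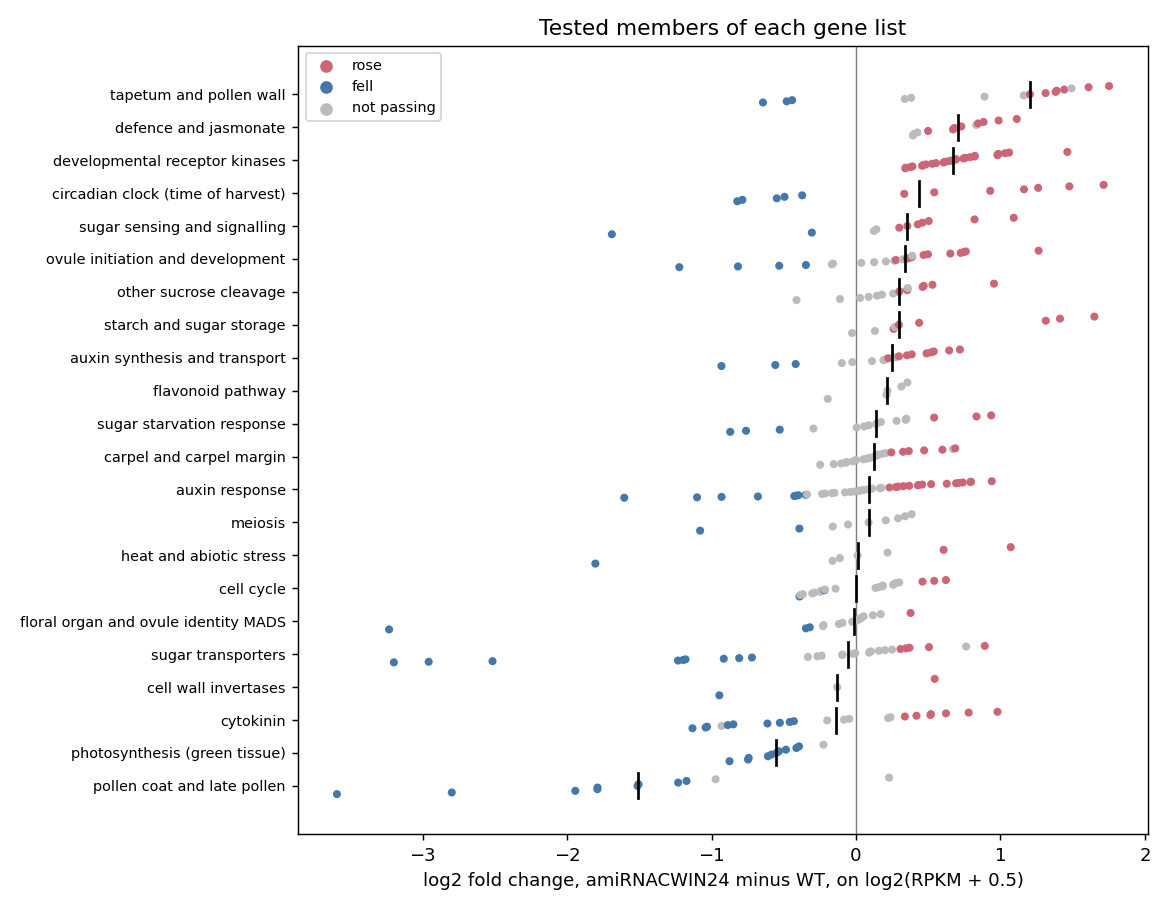
Log2 fold change (amiRNACWIN24 minus WT, on log2(RPKM + 0.5)) of each tested member of the 22 nuclear gene lists, one line per list, with rises in red, falls in blue, members that did not pass in grey and the list median as a black bar. All 26 developmental receptor kinases lie above 0 and 9 of 11 late pollen genes are blue, with medians of 0.67 and -1.51.

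Families defined by a word in the gene description were tested beside the lists, and 13 of 27 passed camera. With an estimated correlation 0 passed (smallest adjusted p = 0.6), and 0 had an unadjusted p under 0.05. Ribosomal protein genes fell, with 237 of 325 down and 7 up (adjusted p = 1.6e-24; adjusted p = 0.6 with an estimated correlation), and with the length trend removed 78 fell and 3 rose. Disease resistance genes rose, with 89 of 109 up and 2 down (adjusted p = 2e-13), as did receptor kinases, with 66 of 90 up and 7 down (7.2e-08), and calmodulin-related genes, with 27 of 50 up and 5 down (0.0045; adjusted p = 0.6 with an estimated correlation for all of these). Their counts with the length trend removed were 30 up and 1 down, 20 up and 6 down, and 18 up and 2 down. Of 10 oleosin family genes 7 fell and 0 rose (0.00042), and of 23 MADS family genes 7 fell and 1 rose (0.0047; adjusted p = 0.6 with an estimated correlation for both). After removal of the length trend 7 oleosin genes fell and 3 rose, and 7 MADS genes fell and 2 rose. Under median-of-ratios scaling 14 MADS genes fell and 1 rose. The other 7 that passed lost their call with the length trend removed: lipid transfer (30 of 60 down, 1 up), auxin-responsive (29 of 62 down, 4 up), histone-related (46 of 97 down, 18 up), arabinogalactan (13 of 46 down, 3 up) and peroxidase (13 of 57 down, 4 up) genes, cytochrome P450 genes (51 of 113 up, 10 down) and heat shock protein genes (11 of 34 up, 1 down). Their adjusted p was 4.7e-06 to 0.017, or 0.6 to 0.78 with an estimated correlation, and the peroxidase call also ended without WT replicate 2 or amiRNACWIN24 replicate 4. Leaving out WT replicates 1 and 2 together ended the heat shock and peroxidase calls, quantile normalization and leaving out overlapping genes the arabinogalactan and peroxidase calls, no filter the cytochrome P450 call, a minimum of 5 RPKM the auxin-responsive call, and removal of length and GC trends together the MADS call. After removal of the length trend alone the counts up and down were 10 and 12 for lipid transfer, 8 and 12 for auxin-responsive, 13 and 13 for histone-related, 4 and 8 for arabinogalactan, 6 and 8 for peroxidase, 25 and 15 for cytochrome P450 and 3 and 1 for heat shock protein genes. Without WT replicate 1 the arabinogalactan falls numbered 22, and under quantile normalization 22 heat shock protein genes rose. The remaining 14 families did not pass (adjusted p from 0.064 to 0.89): of 114 pectin-related genes 23 rose and 28 fell, of 106 MYB genes 28 and 15, of 85 bHLH genes 27 and 5, of 46 WRKY genes 14 and 4, of 45 NAC genes 13 and 7, of 16 ethylene response genes 6 and 2, and of 213 F-box genes 28 and 37. The counts up and down were 1 and 6 of 17 expansins, 15 and 4 of 38 UDP-glucose-related genes, 2 and 6 of 36 glutathione S-transferases, 5 and 2 of 19 xyloglucan endotransglucosylases, 37 and 13 of 97 glycosyl hydrolases, 7 and 11 of 43 genes named sugar transporter, and 41 and 29 of 158 genes matched by the word thionin, most of them enzymes with methionine in their name. Leaving out WT replicate 1 raised the glutathione S-transferase falls to 11 and lowered the rises in genes named sugar transporter to 4, and leaving out WT replicate 3 lowered the WRKY rises to 9 and the expansin falls to 3. Rises in ethylene response genes numbered 3 without WT replicate 4 or amiRNACWIN24 replicate 1 or 2, and without amiRNACWIN24 replicate 3 there were 8 NAC rises and 2 in genes named sugar transporter.

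The fold changes were set beside those in the authors' deposited table. Over 19070 tested genes with a value in both, Pearson's r across genes, which are not independent replicates, was 0.933 and 91.6% had the same sign. The authors' deposited table calls 8068 of these genes at an FDR under 0.05, against 9601 here, and 7477 were called in both, 7475 with the same sign. The authors' deposited table has more falls (4227) than rises (3841) among these genes, while the calls here over all tested genes were 5611 rises and 3998 falls, or 5251 rises and 5247 falls under median-of-ratios scaling. The median difference between the log2 fold changes here and those in the authors' deposited table was 0.089. With the length trend removed from the values here, over 18982 genes, r was 0.778 and 72.3% had the same sign. Then 3497 genes were called in both, 3433 with the same sign and 64 with the opposite sign. CWINV4 has a log2 fold change of -1.06 and CWINV2 one of -3.72 in the authors' deposited table, with an FDR of 0.0022 for CWINV2. In the RPKM values CWINV2 exceeded 6 reads in WT replicate 1 only (180 reads). Expression levels were compared as well: the larger group mean of RPKM against the maximum group mean in the authors' deposited table. Genes with either value at 1 or more were used. These levels, not the fold changes, differed by more than 2-fold for 213 of 5500 genes that overlap a gene on the other strand (3.87%). Among 13193 genes without an overlap 63 did so (0.48%). Fisher's exact test gave an odds ratio of 8.4 (p = 3.2e-61).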

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

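No test in this part was chosen after its result was seen. The 118 named genes gave 236 groups of 4 libraries, in which the highest or lowest library was compared with its nearest neighbour (Dixon's test on the gap over the range). Chance alone picks about 1 in 20 groups, and 7 of the 236 were picked.

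CWINV2 read 2.75 RPKM in WT replicate 1 and 0.0161 to 0.0317 RPKM in the other WT libraries. DIR1 read 14.4 RPKM in amiRNACWIN24 replicate 3 and was listed at 0 in the other amiRNACWIN24 libraries, as was AT5G08820, which read 0.239 RPKM in that library. HKL3 read 1.54 RPKM in amiRNACWIN24 replicate 1 and 0.951 to 1.01 RPKM in the others of its group. LHCB2.1 read 628.8 RPKM in amiRNACWIN24 replicate 4 against 546.3 to 548.9 RPKM. PSAJ read 0.290 RPKM in amiRNACWIN24 replicate 2 and was listed at 0 in the others, and ORF149 read 3.31 RPKM in the same library against 2.19 to 2.35 RPKM. PSAJ and ORF149 are encoded in the organelles, whose transcripts were higher in amiRNACWIN24 replicate 2 than in the other amiRNACWIN24 libraries (0.127% of the RPKM sum chloroplast-encoded, against 0.011% to 0.013%).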

How the results depend on the processing

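The tests with the exon length trend, with length and GC, without overlapping genes, with voom and without WT replicates 1 and 2 were chosen after the results were seen. The cause of the changes listed here was not tested except where fewer genes or libraries were used. Over all alternatives 140 values of the main results stayed the same, which for counts means within 1.5 times and for the targeted genes the same direction and side of the threshold. Direction and side were kept by 2356 gene values (each named gene under each alternative) and 761 list values, while 66 gene and 51 list values fell short of the threshold, 10 and 5 passed it newly, and 19 and 24 turned direction. Leaving out 1 library moved the genes called up between 4667 (without amiRNACWIN24 replicate 3) and 5670 (without amiRNACWIN24 replicate 2) and those called down between 3290 (without WT replicate 2) and 4484 (without WT replicate 1). Median-of-ratios scaling gave 50% of calls up against 58.4%.

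With the length trend removed 5573 genes differed, 2877 up; with length and GC, 5671, 2873 up. Without overlapping genes 2635 of the 12980 genes then tested were down. At least 1.5-fold, 3785 differed, 2121 up and 1664 down. With the estimated correlation 0 lists passed. Against the authors' deposited table r was 0.698 over all genes with a value. The CWINV2 difference ranged from -0.79 to 0.10 when single libraries were left out, reversing without WT replicate 1, and was 0.092 without WT replicates 1 and 2. CWINV1 ranged from -0.39 to 0.20, reversing without WT replicate 1 or 2 or amiRNACWIN24 replicate 4, and was 0.13 with array weights and 0.37 without WT replicates 1 and 2.

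With the length trend removed, and with length and GC, these turned direction in their median or in camera: sucrose cleavage (median 0.017 and 0.015), sugar sensing (0.067 and 0.058), starvation (-0.12 and -0.13), auxin synthesis and transport (-0.059 and -0.070), auxin response (-0.14 and -0.099), TPS1 (-0.25 and -0.25), TPS10 (-0.086 and -0.088), ABCB1 (-0.16 and -0.18), ZYP1B (-0.037 and -0.039), MSH5 (-0.050 and -0.047) and HSP101 (-0.24 and -0.27), and, with length and GC together only, the identity MADS list (0.063). The same held for meiosis and flavonoid lists with no filter (0.095 and -0.0080), heat with quantile normalization (0.080), cell cycle and meiosis without overlapping genes (0.16 and 0.15), and without WT replicates 1 and 2 for flavonoid (-0.0038), heat (-0.033), F3H (-0.0038) and CHS (-0.034). With single libraries left out the medians ranged from -0.0012 to 0.28 for starvation, -0.11 to 0.069 for cell cycle, 0.075 to 0.31 for flavonoid and -0.11 to 0.11 for heat.

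The replicate numbers do not pair the samples: deviations of same-numbered libraries correlated at -0.27, 0.14, -0.32 and 0.53, and only number 4 correlated best with its own. With the replicate block 5581 genes were up and 3590 down, and 1 flavonoid gene rose. Of the named genes 1 fell short of the threshold with this block and 1 passed it newly. CWINV2, below the filter, was not run with a minimum of 5 RPKM, without the trend, with array weights, with trend removal, without overlapping genes or in voom, and organelle lists, without exon lengths, not with trend removal. Depth limits CWINV2, CWINV5 and CWINV6, at 0 to 6 reads outside WT replicate 1.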

Other observations

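The gene groups in the next paragraph, and the tests of a later bud stage in WT and of a loss of ovule tissue, were chosen after the results were seen, as were removal of the length trend and leaving out WT replicates 1 and 2.

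Of the genes grouped here as the indole glucosinolate pathway all 11 that were tested rose in limma (median log2 1.06). SOT18 in this group is annotated for desulfo-glucosinolates with no branch named. The annotations of SUR1, UGT74B1, SOT16 and SOT17 name no branch either, so the rise is not shown to be specific to the indole branch. MYB122, CYP81F2, IGMT1 and IGMT2 were below the filter and not tested. CYP79B3 went from 3.83 ± 0.175 to 15.7 ± 1.41 RPKM, CYP83B1 from 41.9 ± 5.89 to 106 ± 13.2 RPKM and the sulfotransferase SOT17 from 3.59 ± 1.04 to 10.9 ± 1.56 RPKM (SD, n = 4 in each group), beside CYP79B2 and IGMT5. Camera gave p = 7.9e-07, or p = 0.08 with an estimated correlation, and with the length trend removed 10 of 11 rose (median 1.22, p = 2.1e-09, or 0.045 with an estimated correlation). Of 9 jasmonate synthesis genes 7 rose, AOC3 from 12.7 ± 4.47 to 39.7 ± 12.9 RPKM (camera p = 0.00078, or p = 0.16 with an estimated correlation), and 7 rose with the length trend removed. These were not the same 7 genes. The calls of LOX3 and LOX4 ended (log2 0.37 and 0.36), and AOC1 and AOC4 passed newly (log2 0.72 and 0.45). Of 8 type-A response regulators, all of them members of the cytokinin list, 7 fell (median -0.87; camera p = 6.9e-06, or p = 0.0035 with an estimated correlation), ARR15 from 11.1 ± 1.42 to 5.23 ± 1.33 RPKM, and 6 fell with the length trend removed (p = 3.1e-06, or p = 0.0082 with an estimated correlation). These p-values are for groups picked from the same data and are not adjusted.

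Of the 35 splits of the 8 libraries into 4 and 4, only 1, the real split, called as many as 9609 genes. The highest other split called 1. A share of 1 in 35 is the smallest that these splits allow. Every other split mixes the genotypes, so their difference adds to the spread within groups and leaves few calls. The splits therefore cannot tell an effect of the genotype from any other difference between the WT and amiRNACWIN24 libraries.

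Longer genes were higher and shorter genes lower in amiRNACWIN24, at 0.449 log2 units per doubling of exon length. With short transcripts of ribosomal proteins, pollen, lipid transfer and oleosins left out (444 of 18994 genes), the slope was 0.444. The trend therefore lay in the other genes too. Few genes were left out, so a large drop of the slope was unlikely from the start. Organelle-encoded genes have no exon length here and were in neither slope. A length bias of RNA or library preparation that differs between the genotypes' libraries cannot be told apart from an effect of the genotype: the slope was 0.397 in the lowest of 3 classes of mean expression, and 0.473 and 0.482 in the others, but all 4 WT slopes lay below 0 and all 4 amiRNACWIN24 slopes above 0, and the labels give no batch. The many receptor kinases that rose and ribosomal protein genes that fell may therefore be partly technical.

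Late pollen genes were lower in amiRNACWIN24. More late pollen RNA in WT replicates 1 and 2 alone is argued against by the median of -1.54 without them, and the length trend as the whole cause by the median of -1.35 after its removal. A later mix of bud stages in the WT pools stays open: the tapetum list, which an earlier stage in amiRNACWIN24 might raise, had a median of 1.204 with 7 of 15 up and 3 down, but 0.64 with 1 up and 3 down without WT replicates 1 and 2. The meiosis list, which it might raise too, had a median of 0.087 with 0 of 9 up, 2 down and 7 that did not pass. A direct effect of the genotype on pollen was not tested apart from stage.

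STK fell by 3.23 on the log2 scale. The lowest of INO, BEL1, ATS and SPL/NZZ was INO at -1.22, above STK by more than 2 SE of the difference (0.388). ATS stood at -0.53, SPL/NZZ at -0.35 and BEL1 at 0.39. These values argue against a loss of tissue that lowers all of these genes as much as STK. How far each gene tracks ovule tissue in whole buds was not measured, so a loss of ovule tissue is not excluded. The length trend is argued against by a log2 fold change of -3.48 after its removal. A candidate explanation that stays open and untested is silencing of the endogenous gene by the transgene's copy of its promoter, or another change in this single line.

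The clock genes PRR5, TOC1, GI and ELF3 rose while CCA1, LHY, PRR9, RVE8 and BOA fell, and the collection times of the buds are not given in the labels. LCR11 and RALFL15 read 12.8 and 10.7 RPKM in WT replicate 1 and at most 0.238 and 0.279 RPKM in the other libraries.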
